A study of Mus musculus with 46 samples.

How the data were processed

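The signal in every table was the raw count of fragments per gene or exonic part, as deposited by the authors, and no scaling had been applied before deposit. The unit of each table was the count, per the file headers. For spleen, ovary and lung the tables held 49315 genes, and for kidney 55401 genes counted with featureCounts 2.0.1 on Ensembl release 102, per the file headers. For bone marrow and liver they held 425461 exonic parts of 48005 gene identifiers, in which overlapping genes were merged. Parts were summed per gene, so a read spanning several parts counted more than once, and genes that overlap others could not be separated. Per the submitters' processing notes, reads were aligned to mm10 with STAR and tested with DESeq2, without version numbers. Reads were not aligned again, and nothing was known of the alignment beyond these notes. Gene symbols, positions and 3' UTRs came from GENCODE M21 (GRCm38).

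The comparisons, gene lists, alternatives and rule for naming genes were fixed from the labels before the data were examined. The main test was the edgeR 4.0.16 quasi-likelihood F test with robust dispersions, TMM scaling and the filterByExpr filter. It was run in each tissue as KO minus WT, with Benjamini-Hochberg adjustment over all tested genes, and genes with adjusted p below 0.05 were called. DESeq2 1.42.0, limma 3.58.1 and R 4.3.3 served for the second test, the list tests and all fits. Genes named were Zfp36l2, Zfp36 and Zfp36l1 in every tissue. In each tissue up to 8 called genes with the largest log2 fold change up, up to 8 down and up to 6 others with the smallest p were added. These needed a mean of at least 1 CPM in a genotype, no overlap of KO and WT libraries and a symbol that was not that of a predicted gene, of Xist or of a Y-linked gene. Where fewer than 5 genes were called, all were named. For each list described, up to 4 members with the smallest p could be named, and up to 12 genes called in the same direction in 3 or more tissues and up to 8 of the test between tissues were added. Some genes that this rule picked are not reported here.

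Gene lists for cell types and pathways were written from general knowledge. They were tested with limma's camera on voom values at a preset correlation of 0.01, adjusted over the lists of a tissue. Each was tested again with the correlation estimated from the data and with fry. The effect of genotype between tissues was tested in 1 edgeR model of all 46 libraries with an F test of the interaction. The UAUUUAU motif was tested in the longest 3' UTR of each gene with a logistic model on UTR length and expression, adjusted over the tissues and directions. Overlaps between tissues were set against the hypergeometric expectation. Standard errors were derived from the edgeR F statistics, and CPM values used TMM-scaled totals.

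Alternatives fixed beforehand were DESeq2, RLE scaling, no filter, a mean count of at least 50, 1 model of all tissues, age or a sex score as covariate, a block for the replicate number, each library left out in turn, calls at other levels, and other motifs and motif tests. The block could not be fitted in lung. Chosen after the data were seen were 1 exonic part per gene, the fits without 2 libraries in kidney and in liver, and AU content in the motif model. The deposited table of upregulated genes was to be compared by tissue, but it named no tissue, so genes called higher in any tissue were used. In bone marrow the deviations of KO and WT libraries with the same replicate number from their group means correlated with r = 0.175 to 0.388 in the 5 pairs, so the numbers were taken to pair these libraries. The pairing came from the data. The labels did not say that a number marks a litter or a day, but same-numbered marrow libraries had the same labelled day, and per the series text most WT and KO pairs came from the same litter. The main test was left unpaired as fixed beforehand. The 2 spleen libraries both labelled WT3 came from different animals and were used as separate replicates. The series text spoke of an ovarian sample of day 13, while the only label with Day 13 was that of spleen WT1. Lung WT4 was labelled Day 7 and its animal Day 8 in bone marrow and kidney. Fits with age used the label of each library.

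As a check of the methods, counts were simulated at the depth and spread of each tissue, and 200 genes per tissue were changed in the KO group. Of genes changed 4-fold the test recovered 95.88% in spleen, 88.3% in ovary, 88.3% in bone marrow, 95.96% in lung, 85.71% in kidney and 87.76% in liver. Of genes changed 2-fold it recovered 50.51%, 65.98%, 62.5%, 62.24%, 8.163% and 19.39% in the same order, so 2-fold changes in kidney and liver were mostly missed. Unchanged genes called were 7 in spleen, 14 in ovary, 8 in bone marrow, 17 in lung, 2 in kidney and 5 in liver. Each gene was drawn on its own, without differences shared by the genes of a library, so recovery in the real data may be lower. The test between tissues recovered 88.5% of 4-fold changes. A shifted gene list was found, with 0 other lists called, and a motif planted at an odds ratio of 3 was measured at 3.18.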

Results

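Poly(A) RNA from 6 tissues of mouse pups lacking Zfp36l2 (KO) was compared with RNA from wild-type pups (WT). Zfp36l2 encodes a zinc finger protein that binds AU-rich elements in the 3' UTR of mRNAs and promotes their decay. The series held 46 libraries: spleen (4 WT and 4 KO), ovary (3 and 3), bone marrow (5 and 5), lung (3 and 3), kidney (3 and 3) and liver (5 and 5). Per the labels, the pups were 6 to 9 days old, except for the donor of spleen library WT1, which was 13 days old. The libraries came from 29 animals, of which 12 gave more than 1 tissue, so the tissues were not independent of each other. Library totals were 26703937 to 45167464 counts in spleen, ovary, lung and kidney. In bone marrow and liver they were 68472691 to 150824063, with reads that span several exonic parts counted more than once. Each gene was tested within its tissue with edgeR, and every difference is given as KO minus WT.

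Zfp36l2 mRNA fell in KO in 5 tissues, most in bone marrow and spleen. In bone marrow it fell from 98.6 ± 14.6 to 4.90 ± 0.851 CPM (mean ± SD over 5 libraries per genotype), a log2 fold change of -4.33 (SE 0.15; edgeR adjusted p = 2.9e-09). In spleen it fell by 4.08 on the log2 scale (SE 0.21; edgeR adjusted p = 9.58e-06), in lung by 2.42 (SE 0.17; 0.00127), in ovary by 2.39 (SE 0.12; 0.000478) and in liver by 2.03 (SE 0.27; 0.00698). Kidney held 82.4 ± 11.4 CPM in WT and 20.9 ± 3.13 CPM in KO, a log2 fold change of -1.98 that did not pass the test (SE 0.19; edgeR adjusted p = 0.0558). In all 6 tissues every KO library lay below every WT library, and chance alone keeps the genotypes apart, in either direction, for 10% of genes when 3 libraries are set against 3. The gene lies on the minus strand of chromosome 17 (84183931 to 84187947, GRCm38). Its 3' exonic part (84183931 to 84187156) held 78.7 CPM in WT and 0.974 CPM in KO marrow, while its 5' part (84187644 to 84187947) held 19.5 and 3.96 CPM. In liver the 3' part held 9.67 and 0.753 CPM and the 5' part 2.07 and 2 CPM, so most of the reads left in KO liver lay at the 5' end. Of its paralogs, Zfp36l1 passed in none of the 6 tissues (log2 fold change 0.09 to 0.46; edgeR adjusted p = 0.127 or more). Zfp36 fell in bone marrow (-1.69, SE 0.43; edgeR adjusted p = 0.0141), where KO and WT libraries overlapped. That call ended when a sex score was added to the model (edgeR adjusted p = 0.112).

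**Figure D1:**
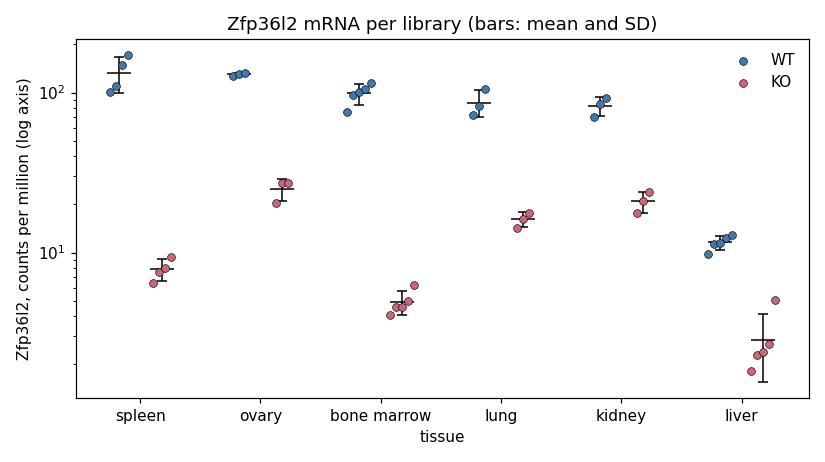
Zfp36l2 mRNA in each library, by tissue and genotype, in CPM.

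Bone marrow of KO pups held little mRNA of platelet genes and less mRNA of neutrophil genes, while bone matrix genes were higher. Ppbp, a chemokine of platelet granules, fell from 59.0 ± 25.7 to 1.78 ± 1.69 CPM (mean ± SD over 5 libraries per genotype). Other platelet genes among the largest falls were Mpig6b (-5.20), Gp6 (-5.15), Treml1 (-5.08), Ly6g6f (-5.06), Kcnj5 (-4.90) and Gnaz (-4.63) (log2 fold change; with Ppbp, SE 0.50 to 0.69; edgeR adjusted p = 8.5e-06 to 0.000432). After Zfp36l2 the smallest p values belonged to stefin genes of neutrophils, Stfa1 (-3.88, SE 0.18; edgeR adjusted p = 4.73e-08), Stfa2l1 (-3.67), BC100530 (-3.06) and BC117090 (-3.83), and to Mrgpra2b (-4.50; edgeR adjusted p = 1.53e-07 for these 4). The stefin genes sit in a cluster of near-identical copies on chromosome 16, and Mrgpra2b has a close copy, so the share of each copy is uncertain. The largest rises were those of Lexm (7.12, SE 0.57; edgeR adjusted p = 2.39e-06), the chemokine genes Ccl8 (5.90; 8.59e-07) and Cxcl9 (4.56; 0.00183), Tcf23 (4.51; 1.85e-06), Sept3 (4.24; 4.78e-07), Pianp (4.17; 1.05e-06) and Igkv7-33 (3.93; 0.00106). WT marrow held 3 counts of Lexm against 487 in KO, a ratio of 165.2 (95% interval 56.19 to 803.8, for counting error only, with reads that can count more than once), and only WT4 of the WT libraries held any. Fgf23, the phosphate-lowering hormone of bone, rose from 0.522 ± 0.722 to 11.2 ± 9.09 CPM (4.4, SE 0.97; edgeR adjusted p = 0.00696). In all, 5187 of 17854 genes were called, 2643 higher and 2544 lower, and DESeq2 called 6055. Leaving out 1 library at a time gave 4324 to 5177 called genes. KO libraries were more often male by their sex score (4 of 5) than WT libraries (2 of 5). With that score in the model 3721 genes were called, of which 3615 were among the 5187.

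The megakaryocyte and platelet list fell as a whole in bone marrow: 13 of 13 measured members fell, all 13 also adjusted over the list alone (median -3.00, camera adjusted p = 3.58e-13, and 0.18 with an estimated correlation). Of the neutrophil list 19 of 20 members fell (median -1.80, camera adjusted p = 1.91e-14, and 0.18 with an estimated correlation), with 19 adjusted over the list alone. Its members with the smallest p values were Mmp8 (-2.60), Retnlg (-2.79), Cxcr2 (-2.28) and Csf3r (-2.48) (edgeR adjusted p = 4.68e-06 to 3.47e-05). Blood stem and progenitor mRNAs were lower (median -0.65, camera adjusted p = 0.0134, and 0.18 with an estimated correlation), 7 of 12 called lower and 1 higher (7 and 3 adjusted over the list alone), among them Kit (-1.62), Cd34 (-1.18) and Flt3 (-0.75) (edgeR adjusted p = 2.58e-06 to 0.000345). The bone list went the other way: 11 of 13 members rose, and 11 adjusted over the list alone (median 1.73, camera adjusted p = 1.05e-08, and 0.18 with an estimated correlation). Col1a1, the main collagen of bone, rose 4.56-fold, and Dmp1 (2.32), Sp7 (1.76) and Alpl (1.49) rose with it (edgeR adjusted p = 3.85e-06 to 1.59e-05). Matrix and fibroblast mRNAs such as Col1a2 (2.20) and Sparc (1.96) (edgeR adjusted p = 3.71e-06 to 3.85e-06) rose in 12 of 18 members, 13 adjusted over the list alone (median 0.94, camera adjusted p = 7.97e-07, and 0.22 with an estimated correlation). Skeletal muscle mRNAs, Myh1 (1.58), Actn3 (1.35) and Atp2a1 (1.21), were also called higher (3 of 12 members, 3 adjusted over the list alone; median 1.18, camera adjusted p = 0.00473, and 0.55 with an estimated correlation). Their KO and WT libraries overlapped (edgeR adjusted p = 0.0223 to 0.0426), and all 3 calls ended without KO4, KO5, WT1, WT2, WT3 or WT5 (edgeR adjusted p = 0.0522 to 0.112), that of Atp2a1 also without KO1 (edgeR adjusted p = 0.0629). With the sex score in the model, or without the filter, all 3 calls ended as well (edgeR adjusted p = 0.0558 to 0.165), and in the model of all tissues those of Flt3, Myh1 and Atp2a1 did (0.0767 to 0.179).

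Among immune cells of the marrow, T and NK cell mRNAs rose in 12 of 17 members and fell in 1 (13 and 1 adjusted over the list alone; median 1.26, camera adjusted p = 2e-04, and 0.55 with an estimated correlation). Trac, the constant region of the T cell receptor alpha chain, rose 6.57-fold, Cd8b1 5.94-fold and Cd3e 4.26-fold (edgeR adjusted p = 6.12e-05 to 0.000654). B cell mRNAs were higher in 8 of 19 members, 8 adjusted over the list alone (median 0.54, camera adjusted p = 0.000389, and 0.55 with an estimated correlation), including Pax5 (0.78), Igll1 (0.69) and Cd22 (0.96) (edgeR adjusted p = 0.00547 to 0.00736). The monocyte and macrophage list went both ways: 9 of 20 members rose and 4 fell (the same 9 and 4 adjusted over the list alone; median 0.49, camera adjusted p = 0.00808, and 0.55 with an estimated correlation). Among its members Siglec1 (2.53), C1qa (1.27) and Mrc1 (1.21) rose (edgeR adjusted p = 7.38e-06 to 4.24e-05), and Lyz2 (-1.66), Ly6c2 (-1.38) and Ccr2 (-0.71), chosen after their values were seen, fell (edgeR adjusted p = 0.000113 to 0.00588). Endothelial mRNAs such as Flt1 (0.85) and Kdr (0.86) (edgeR adjusted p = 0.00152 to 0.00381) rose in 8 of 15 members, 12 adjusted over the list alone (median 0.63, camera adjusted p = 0.000245, and 0.55 with an estimated correlation). mRNAs described elsewhere as targets of the ZFP36 family were lower rather than higher in KO marrow: 11 of 29 fell and 3 rose (14 and 3 adjusted over the list alone; median -0.32, camera adjusted p = 0.0362, and 0.55 with an estimated correlation). The inflammatory mRNAs Il1b (-1.89), Ptgs2 (-2.70) and Ccl3 (-1.98) fell (edgeR adjusted p = 0.00122 to 0.00184), while Hif1a rose by 0.52 (edgeR adjusted p = 0.00231). The neutrophil list fell in the same libraries (median -1.8). Shifts in cell types were not separated from changes of the target mRNAs within cells. Immediate early mRNAs fell in 9 of 19 members and rose in 2 (10 and 2 adjusted over the list alone; median -1.12, camera adjusted p = 0.0024, and 0.55 with an estimated correlation), among them Ier2 (-1.63) and Btg2 (-1.04) lower and Ccn1 (1.59) and Socs3 (0.88) higher (edgeR adjusted p = 0.00206 to 0.00971). The call of Ccn1 ended with the sex score in the model (edgeR adjusted p = 0.092) and that of Hif1a with 1 exonic part per gene (edgeR adjusted p = 0.0508), an alternative chosen after the data were seen. In the model of all tissues those of Ccr2, Pax5 and Igll1 ended (edgeR adjusted p = 0.0867 to 0.267).

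In spleen, platelet mRNAs fell as they did in marrow, and the hormone gene Fgf23 showed the largest rise. Ppbp fell from 355 ± 101 to 5.32 ± 2.01 CPM (mean ± SD over 4 libraries per genotype). Kcnj5 (-7.12), Gp6 (-6.41), Treml1 (-6.39), Ly6g6f (-5.75) and Mpig6b (-5.67) were the other platelet genes among the largest falls (log2 fold change; with Ppbp, SE 0.29 to 0.52; edgeR adjusted p = 9.23e-06 to 4.85e-05). Serpina3b, from a cluster of similar genes on chromosome 12, had 622 counts in WT and 3 in KO, a ratio of 202.7 (95% interval 69.04 to 985.6, for counting error only; edgeR adjusted p = 8.96e-05), and only KO4 of the KO libraries held any. Very small p values also went with the platelet genes Mrvi1 (-2.88), Tubb1 (-4.22), Thbs1 (-3.26), Gp1ba (-3.49) and Rgs18 (-3.06) (edgeR adjusted p = 9.23e-06 to 1.14e-05). Fgf23 rose from 0.0746 ± 0.0641 to 42.8 ± 20.8 CPM, 554-fold (9.11, SE 0.56; edgeR adjusted p = 1.86e-05). The protease inhibitor A2m (5.66), the apolipoprotein L genes Apol10a (5.40) and Apol11a (4.81), C2cd4a (4.95), Krt4 (4.94), the RNA-binding protein gene Elavl2 (4.75) and the metalloprotease gene Mmp3 (4.54) rose as well (SE 0.25 to 0.66; edgeR adjusted p = 1.14e-05 to 0.00145). The Apol genes are neighbouring copies on chromosome 15, so reads could be shared among them. Among 16796 genes, 2262 were called, 1159 higher and 1103 lower, while DESeq2 called 3252. The count was 1227 without KO1, 1331 without KO2, 1260 without WT2 and 1130 without WT3b.

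All 15 of 15 measured members of the megakaryocyte and platelet list fell in spleen, 15 adjusted over the list alone (median -4.19, camera adjusted p = 9.68e-27, and 0.17 with an estimated correlation). Neutrophil mRNAs fell in 17 of 20 members, 19 adjusted over the list alone (median -1.99, camera adjusted p = 1.03e-11, and 0.44 with an estimated correlation), led by Camp (-2.81), Elane (-2.54), Cd177 (-2.13) and Retnlg (-2) (edgeR adjusted p = 0.00419 to 0.0114). Stem and progenitor mRNAs were lower too, 5 of 14 members called lower and 1 higher (6 and 3 adjusted over the list alone; median -0.52, camera adjusted p = 0.0342, and 0.74 with an estimated correlation), among them Slamf1 (-2.16), Kit (-1.46), Myb (-1.07) and Angpt1 (-0.97) (edgeR adjusted p = 0.00083 to 0.00264). Cholesterol synthesis and uptake mRNAs rose in 13 of 19 members, 14 adjusted over the list alone (median 0.87, camera adjusted p = 5.31e-09, and 0.29 with an estimated correlation), such as Insig1 (1.30) and Lss (0.91) (edgeR adjusted p = 0.000921 to 0.00307). Matrix and fibroblast mRNAs rose in 10 of 20, 12 adjusted over the list alone (median 0.53, camera adjusted p = 3.23e-06, and 0.29 with an estimated correlation), with Lum (1.90), Pdgfra (1.59), Pdgfrb (1.15) and Fn1 (1.07) in front (edgeR adjusted p = 0.000511 to 0.00112). Of the mRNAs described as ZFP36 family targets 8 of 28 rose and 1 fell (12 and 2 adjusted over the list alone; median 0.50, camera adjusted p = 0.00494, and 0.26 with an estimated correlation), including Cxcl1 (2.31), Pim1 (1.68) and Hif1a (0.78) (edgeR adjusted p = 0.00324 to 0.00989). Cxcl1 was near the floor, at 0.023 to 0.138 CPM in WT and 0.256 to 0.612 CPM in KO. Targets of p53, Cdkn1a (2.02), Ccng1 (0.71) and Mdm2 (0.63) (edgeR adjusted p = 0.000464 to 0.0122), rose in 5 of 15 members, and 5 adjusted over the list alone (median 0.14, camera adjusted p = 0.0128, and 0.47 with an estimated correlation). Glycolytic mRNAs rose in 3 of 18 members of the hypoxia list, 3 adjusted over the list alone, with Pfkp (0.83) and Eno1 (0.55) (median 0.18, camera adjusted p = 0.0421, and 0.47 with an estimated correlation). Endothelial mRNAs rose in 2 of 16, 2 adjusted over the list alone, namely Flt1 (0.75) and Cdh5 (0.70) (median 0.29, camera adjusted p = 0.00316, and 0.72 with an estimated correlation). The 4 last genes had edgeR adjusted p = 0.00547 to 0.0268. Cdh5 lost its call without KO2 (edgeR adjusted p = 0.05), WT2, WT3a (0.0509) or WT3b, and Pfkp without WT3b (edgeR adjusted p = 0.052 to 0.0748 in the fits without WT2 or WT3b). Calls also ended in the model of all tissues for Lss, Fn1, Cxcl1, Eno1, Pfkp, Flt1 and Cdh5 (edgeR adjusted p = 0.0702 to 0.197) and without the filter for Cd177 and Retnlg (0.0608 to 0.0779). That of Cdh5 also ended with age as covariate (edgeR adjusted p = 0.0783) and with the 2 WT3 libraries summed (0.0559). WT spleens held pancreas mRNA at unequal levels, with Ctrb1 at 70.3 ± 60.9 CPM in WT and 0.205 ± 0.165 in KO, and Cel (-8.49) and Cpa1 (-5.47) (edgeR adjusted p = 0.00722 to 0.0119). KO and WT libraries overlapped for these 3, their calls ended without the filter (edgeR adjusted p = 0.0617 to 0.0893), and the pancreas list did not pass (median -6.95, camera adjusted p = 0.0687, and 0.72 with an estimated correlation).

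In liver, Fgf23 rose from 0.124 ± 0.127 to 8.20 ± 8.86 CPM (mean ± SD over 5 libraries per genotype), a log2 fold change of 6.05 (SE 1.03; edgeR adjusted p = 0.0187). Other large rises were those of the steroid hydroxylase Cyp17a1 (6.04), the acute phase protein Orm1 (5.35), Nnmt (5.07), Mgarp (5.05), Elfn1 (4.89) and the hepcidin gene Hamp (4.58), with SE 0.57 to 1.02 and edgeR adjusted p = 0.00281 to 0.0473. Large falls were those of the stefin genes Stfa1 (-4.21), Stfa3 (-3.98), Stfa2l1 (-3.98) and BC100530 (-3.89) and of the neutrophil genes Chil3 (-3.96), Fcnb (-3.59) and Ngp (-3.53) (SE 0.42 to 0.59; edgeR adjusted p = 0.00281 to 0.00936). Small p values also went with Il17rb (2.41), Fabp4 (2.18), C4a (2.73), Scn8a (4.52), Stfa2 (-3.46) and Slc25a21 (-1.85) (edgeR adjusted p = 0.00281 to 0.00651). Of these, Orm1, C4a, Hamp and the stefin genes have close copies that could share reads. Among 17422 genes, 247 were called, 130 higher and 117 lower, and DESeq2 called 1041. Libraries KO3 and KO5 lay at opposite ends of the first principal component (37.21% of variance), and 100 genes were called without them, an alternative chosen after the data were seen. The count was 133 without KO2, 140 without KO3, 129 without WT1, 63 without WT2, 88 without WT3, 115 without WT4 and 84 without WT5. Of 35 genes named and called in liver, 16 lost the call without WT2 (edgeR adjusted p = 0.0507 to 0.138), 15 without WT3 (0.0532 to 0.136), 13 without WT5 (0.057 to 0.118) and 10 without WT4 (0.0507 to 0.11). Without WT1 9 lost it (edgeR adjusted p = 0.0782 to 0.123), without KO4 8 (0.0546 to 0.088), without KO2 7 (0.0517 to 0.0782), without KO3 7 (0.0511 to 0.0953) and without KO5 2 (0.0548 to 0.0607). Each of Cyp17a1, Fgf23, Nnmt, Mgarp, Elfn1 and Hamp was among them in at least 1 fit. Calls of Nnmt and Hamp also ended without the filter (edgeR adjusted p = 0.0788 to 0.102) and with age or with the sex score as covariate (0.0517 to 0.061), and that of Hamp without KO3 and KO5 (0.0873).

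Neutrophil mRNAs fell in KO liver in 14 of 20 members, 16 adjusted over the list alone, where 1 was higher (median -2.78, camera adjusted p = 2.77e-23, and 0.097 with an estimated correlation), including Cebpe (-3.24) and Cd177 (-3.11) (edgeR adjusted p = 0.00651 to 0.00715). The hypoxia and glycolysis list rose in 4 of 18 members, and in 17 adjusted over the list alone (median 1.30, camera adjusted p = 3.13e-15, and 0.097 with an estimated correlation). Its called members were Ankrd37 (3.31), Aldoa (1.53), Egln3 (1.39) and Pgk1 (1.30) (edgeR adjusted p = 0.0286 to 0.0484). Of the acute phase list, Orm1 and Orm2 (4.01; edgeR adjusted p = 0.0159) rose among 15 members, 5 adjusted over the list alone (median 0.56, camera adjusted p = 4.04e-06, and 0.097 with an estimated correlation). Platelet mRNAs fell in 2 of 13 members, Ppbp (-1.90) and Gp9 (-1.88) (edgeR adjusted p = 0.0231 to 0.0377), and in 7 adjusted over the list alone (median -1.54, camera adjusted p = 4.15e-07, and 0.21 with an estimated correlation). No cholesterol synthesis mRNA passed over all genes, and 1 of 18 was lower adjusted over the list alone (median -0.67, camera adjusted p = 9.15e-06, and 0.34 with an estimated correlation). Fdft1 (-1.18) and Hmgcs1 (-1.08) had edgeR adjusted p = 0.0649 to 0.185. ZFP36 family target mRNAs had a median of 0.34 with no call over all genes and 6 of 31 higher adjusted over the list alone (camera adjusted p = 0.0014, and 0.21 with an estimated correlation), with Il1b at 1.83 and Vegfa at 1.11 (edgeR adjusted p = 0.0694 to 0.0857). Mature hepatocyte mRNAs moved apart: Cyp2e1 fell (-1.91) while Baat (1.78) and Uox (1.40) rose (edgeR adjusted p = 0.0118 to 0.0185), and the list did not pass (median 0.02, camera adjusted p = 0.684, and 0.83 with an estimated correlation). The calls of Ankrd37, Aldoa, Egln3, Pgk1, Ppbp and Gp9 each ended in some of the fits without 1 library given above, as did those of Orm2 and Uox. With 1 exonic part per gene, an alternative chosen after the data were seen, those of Pgk1 and Egln3 ended (edgeR adjusted p = 0.0529 to 0.054), and with age as covariate those of Egln3 and Gp9 (0.0525 to 0.0672). Without KO3 and KO5 those of Aldoa, Pgk1, Egln3, Ppbp and Gp9 ended (edgeR adjusted p = 0.0696 to 0.108).

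In the ovary, Pabpn1l, an oocyte poly(A)-binding protein gene with a part in maternal mRNA decay, fell from 14.1 ± 3.09 to 0.0910 ± 0.0338 CPM (mean ± SD over 3 libraries per genotype), 150.4-fold (-7.23, SE 0.31; edgeR adjusted p = 0.000319). It fell with the genes of the transcription factors Otx1 (-3.70), Insm1 (-3.40), Pax6 (-2.62) and Sebox (-2.44), the germ cell gene Dppa2 (-2.52), Crym (-2.93) and Pde6b (-2.64), with SE 0.32 to 0.63 and edgeR adjusted p = 0.00551 to 0.0487. Jag1, a Notch ligand, rose from 75.1 ± 4.17 to 215 ± 18.4 CPM (1.52, SE 0.09), and Mb21d2 (1.25), Atp2b3 (2.68), Crybg1 (2.57) and Extl1 (1.93) had similarly small p values (edgeR adjusted p = 0.000478 to 0.000916). The largest rises were those of AF366264 (4.36), Speer4f2 (3.98), Satl1 (3.93), Myt1 (3.21), Epp13 (3.13), Otop3 (3.12), Ptpn20 (3.10) and Bglap3 (2.88) (SE 0.22 to 0.68; edgeR adjusted p = 0.00142 to 0.0404). Of these, AF366264, Speer4f2 and Bglap3 have close copies that could share reads. Among 18727 genes, 315 were called, 243 higher and 72 lower, and DESeq2 called 1061. The count was 209 without KO1, 475 without KO2, 47 without WT1, 25 without WT3 and 38 without WT4. Interferon response mRNAs such as Isg15 (1.65) and Cxcl10 (1.81) rose (edgeR adjusted p = 0.0258 to 0.0499), in 3 of 19 members and in 13 adjusted over the list alone (median 0.79, camera adjusted p = 2.56e-08, and 0.26 with an estimated correlation). Cdh5 (0.37) and Pfkfb3 (0.84) rose as the only called members of their lists (edgeR adjusted p = 0.0276 to 0.0444). For the 16 endothelial mRNAs, 9 were higher adjusted over the list alone (median 0.33, camera adjusted p = 2.36e-07, and 0.26 with an estimated correlation), and for the 18 of the hypoxia list 2 (median 0.21, camera adjusted p = 0.00111, and 0.61 with an estimated correlation). No granulosa cell mRNA passed over all genes: the list had a median of -0.24 (camera adjusted p = 0.0273, and 0.62 with an estimated correlation), with Inhbb at -0.70 and 1 member, Gatm (0.41), higher adjusted over the list alone. The 11 adipocyte mRNAs all had lower values in KO, with none called (median -0.48, camera adjusted p = 0.0121, and 0.68 with an estimated correlation). The ZFP36 family target list had no call over all genes and 4 of 24 higher adjusted over the list alone (median 0.16, camera adjusted p = 0.00523, and 0.35 with an estimated correlation), with Notch1 at 0.40 and Vegfa at 0.35 (edgeR adjusted p = 0.0913 to 0.0931). Of 26 genes named and called in ovary, 16 lost the call without WT3 (edgeR adjusted p = 0.0504 to 0.205), 15 without WT1 (0.0522 to 0.223), 15 without WT4 (0.0672 to 0.24), 9 without KO1 (0.0501 to 0.104), 6 without KO4 (0.0558 to 0.103) and Cxcl10 without KO2 (0.0626). Pabpn1l, Jag1, Mb21d2, Atp2b3, Crybg1, Extl1, Epp13, Speer4f2, AF366264 and Bglap3 were not among them. In the model of all tissues 12 calls ended (edgeR adjusted p = 0.059 to 1), among them those of Extl1, Dppa2, Myt1, Pax6, Sebox, Pde6b, Ptpn20, Isg15, Cxcl10, Cdh5 and Pfkfb3, and without the filter that of Satl1 (0.0936). At a mean count of at least 50 those of Insm1 and Cxcl10 ended (edgeR adjusted p = 0.0534 to 0.0583), and with RLE scaling that of Cxcl10 (0.0502).

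In lung, 4 genes were called by edgeR, out of 17730 tested. Apol11b, an apolipoprotein L gene, rose from 3.61 ± 0.689 to 37.6 ± 5.11 CPM (mean ± SD over 3 libraries per genotype; 3.38, SE 0.19; edgeR adjusted p = 0.000381). The predicted gene Gm32051 rose by 4.07 on the log2 scale (SE 0.39; edgeR adjusted p = 0.014) and Bmp6, a growth factor gene, by 1.11 (SE 0.12; 0.0234), while Zfp36l2 fell. KO and WT libraries did not overlap for these 4 genes, as 10% of genes do by chance. Gm32051 lost its call without KO3 (edgeR adjusted p = 0.0638) or WT4 (0.0584), and Bmp6 without KO1 (0.0686), KO2 (0.145), KO3 (0.146), WT4 (0.0783) or WT5 (0.0769). The call of Bmp6 also ended in the model of all tissues (edgeR adjusted p = 0.472) and with the sex score as covariate (0.0687). DESeq2 called 774 genes in lung, and 3481 had an unadjusted edgeR p below 0.05. Library WT5 held counts for 36003 genes, against 24184 to 28748 in the other 5, and without it 3 genes were called. Counts were 2 without KO3, 2 without WT4 and 632 without WT2. No list member passed over all genes. Platelet mRNAs Treml1 (-2.75) and Tubb1 (-2.41) (edgeR adjusted p = 0.0896 for both) belonged to a list with 9 of 15 members lower and 1 higher adjusted over the list alone (median -1.23, camera adjusted p = 1.94e-05, and 0.51 with an estimated correlation). Of 20 monocyte and macrophage mRNAs 8 were higher adjusted over the list alone (median 0.60, camera adjusted p = 1.69e-05, and 0.51 with an estimated correlation), with Marco (1.70) and Csf1r (0.67) (edgeR adjusted p = 0.136 to 0.14). The interferon list had a median of 1.06 over 20 mRNAs, with 0 higher adjusted over the list alone (camera adjusted p = 0.00091, and 0.85 with an estimated correlation), with Cxcl10 at 2.37 (edgeR adjusted p = 0.175). Alveolar type 2 mRNAs had 2 of 14 higher adjusted over the list alone (median 0.27, camera adjusted p = 0.0115, and 0.65 with an estimated correlation), with Fasn (1.17) and Abca3 (0.79) (edgeR adjusted p = 0.15 to 0.152).

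In kidney, Epo, the erythropoietin gene, rose from 0.620 ± 0.288 to 26.3 ± 4.46 CPM (mean ± SD over 3 libraries per genotype), 41.8-fold (5.39, SE 0.38; edgeR adjusted p = 0.0169). The stefin genes Stfa1 (-4.16, SE 0.27; edgeR adjusted p = 0.0164) and BC100530 (-2.99, SE 0.27; 0.0482) fell, though reads of these near-identical copies could be shared. These were the 3 genes called out of 17870, 1 higher and 2 lower, and KO and WT libraries did not overlap for any of them, as 10% of genes do by chance. DESeq2 called 69 higher and 30 lower, and 796 genes had an unadjusted edgeR p below 0.05. Libraries KO5 and WT2 stood at the same end of the first principal component (58.3% of variance), and without them, an alternative chosen after the data were seen, 191 genes were called. All 3 calls ended without KO3 (edgeR adjusted p = 0.158 to 0.25), KO5 (0.076 to 0.281), WT3 (0.126 to 0.209) or WT4 (0.0701 to 0.143), with 0 genes called in each of these fits, and that of BC100530 without KO4 (0.128), in the model of all tissues (0.144) and at a mean count of at least 50 (0.0512). Without KO4 the count was 6, and without WT2 it was 7. By their sex score 2 of 3 KO libraries were male and all 3 WT libraries female, and with that score in the model no gene was called (edgeR adjusted p = 0.263 to 0.955 for the 3 genes). Neutrophil mRNAs, Retnlg at -2.47 and S100a8 at -1.74 (edgeR adjusted p = 0.229 to 0.34), had 13 of 19 members lower adjusted over the list alone and none called over all genes (median -1.67, camera adjusted p = 1.26e-20, and 0.13 with an estimated correlation). The hypoxia and glycolysis list had 10 of 18 members higher adjusted over the list alone (median 0.61, camera adjusted p = 2.35e-15, and 0.1 with an estimated correlation), with Adm (0.81), Eno1 (0.80), Aldoa (0.72) and Slc2a1 (0.60) (edgeR adjusted p = 0.448 to 0.702). Mitochondrially encoded mRNAs such as mt-Nd4 (-1.21) and mt-Co1 (-0.99; edgeR adjusted p = 0.594 to 0.881) had 5 of 13 lower adjusted over the list alone (median -0.64, camera adjusted p = 2.92e-10, and 0.13 with an estimated correlation). Proximal tubule mRNAs had 3 of 16 higher and 1 lower adjusted over the list alone (median 0.30, camera adjusted p = 0.00104, and 0.32 with an estimated correlation), with Slc7a13 (1.5) and Slc3a1 (0.89) (edgeR adjusted p = 0.42 to 0.634). With no member called over all genes, other lists of cell types in or near the kidney passed too: distal nephron and collecting duct (median 0.16, camera adjusted p = 1.82e-05, and 0.13 with an estimated correlation), podocytes (median -0.39, camera adjusted p = 0.00575, and 0.32 with an estimated correlation) and adrenal gland (median -0.48, camera adjusted p = 0.0245, and 0.15 with an estimated correlation).

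**Figure D2:**
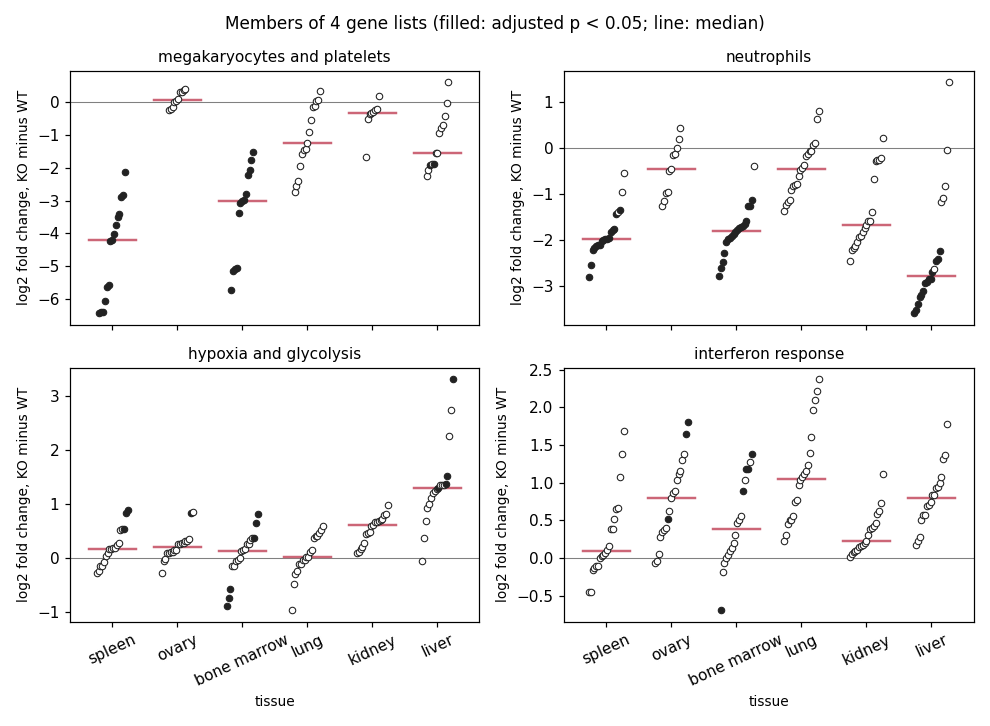
Log2 fold changes (KO minus WT) of the members of 4 gene lists in each tissue. Filled points passed edgeR over all genes, and lines mark medians.

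The effect of the KO differed between tissues for 2516 of 22178 genes (edgeR, 1 model of all tissues). The model treated libraries as independent, though 12 of 29 animals gave more than 1 tissue. It also used 1 dispersion per gene, while the biological coefficient of variation ran from 0.16 in ovary to 0.377 in liver. In it 2056 genes were called in liver and 66 in ovary, against 247 and 315 in the fits by tissue. Its p values and SE are therefore approximate. Cda, a cytidine deaminase gene, had log2 fold changes of 3.85 in spleen (SE 0.24) and 3.27 in bone marrow (0.21), against -0.15 in ovary, -0.91 in lung, 0.46 in kidney and -0.98 in liver (edgeR adjusted p = 4.04e-16). Bmp1, a procollagen protease gene, was at 1.73 in bone marrow (SE 0.13) and -0.56 in liver (0.13; edgeR adjusted p = 9.2e-10). The platelet genes Pf4 (-5.64 in spleen, -3.39 in bone marrow, 0.21 in kidney) and Itga2b (-3.72, -2.81 and -0.27) fell in spleen and bone marrow. Mmrn1, also of platelets, was at -4.15 in spleen, -1.30 in liver (SE 0.26) and -0.44 in bone marrow (SE 0.24). Pls1 was at -3.96 in spleen and 0.87 in ovary, and F13a1, a clotting factor gene, at -2.98 in spleen and 1.54 in kidney. These 5 genes had edgeR adjusted p = 9.49e-10 each. Zfp36l2 itself differed, from -4.34 in bone marrow to -1.96 in kidney (edgeR adjusted p = 3.3e-09). Without bone marrow 687 genes were called. Tissue was tied to the sample set of animals and, in part, to the counting method, so part of these differences could not be told from batch.

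**Figure D3:**
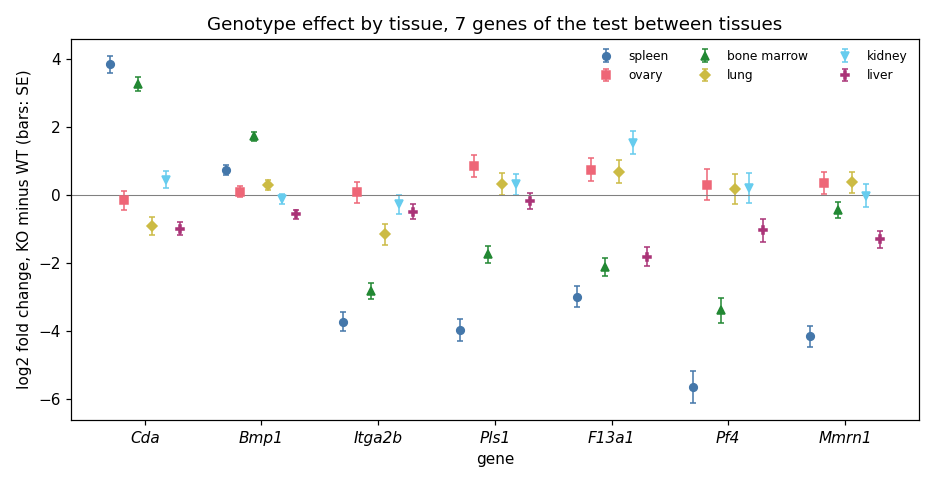
Log2 fold changes (KO minus WT, with SE) by tissue of the 7 genes with the smallest p values in the test between tissues.

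Few genes were called in more than 2 tissues. In the same direction, 32 were called higher and 49 lower in 3 tissues, 3 and 2 in 4 tissues, and 1 lower in 5 tissues. With 4 called genes in lung, 3 in kidney and simulated 2-fold changes mostly missed in kidney and liver, these numbers were limited beforehand. They do not show that few genes changed. Of 6487 genes called in any tissue, 1361 were called in the same direction in 2 or more, and 76 in opposite directions. Besides Zfp36l2, which fell in 5 tissues, the genes called in 4 tissues were the stefin genes Stfa1 and BC100530 (lower in spleen, bone marrow, kidney and liver), Apol11b and Gm32051 (higher in spleen, bone marrow, lung and liver) and Clca3a1, a chloride channel accessory gene (higher in spleen, ovary, bone marrow and liver). Apol11b rose 15.7-fold in spleen, 11.6-fold in bone marrow and 7.28-fold in liver (edgeR adjusted p = 0.000206, 4.61e-07 and 0.0117), with a log2 fold change of 3.11 in kidney (edgeR adjusted p = 0.0558). Gm32051 rose by 3.45 in spleen, 3.63 in bone marrow and 3.31 in liver (edgeR adjusted p = 0.000172, 0.000107 and 0.0137). Clca3a1 rose by 0.68 to 1.11 (edgeR adjusted p = 0.000706 to 0.0319). Its calls ended without WT2 or WT3b in spleen, without WT1, WT3, WT4 or KO1 in ovary, and in liver without any 1 library but KO1 or KO5 (edgeR adjusted p = 0.0619 to 0.172 over these fits). They also ended with age as covariate in spleen and liver (edgeR adjusted p = 0.0513 to 0.0688), in the model of all tissues in ovary (0.527), and in liver without the filter (0.0732), with 1 exonic part per gene (0.0639) and without KO3 and KO5 (0.0514). The spleen call of BC100530 ended without the filter (edgeR adjusted p = 0.0582). In spleen, bone marrow and liver Stfa2l1, Stfa2, Stfa3, BC117090, Mpig6b and Ppbp fell and the collagen hydroxylase gene Plod2 rose (1.13, 1.89 and 1.54; edgeR adjusted p = 0.000609, 1.68e-06 and 0.0473), as did Fgf23. The liver call of Plod2 ended without any 1 library but KO1 (edgeR adjusted p = 0.0552 to 0.131), with age or the sex score as covariate (0.063 to 0.0712), with 1 exonic part per gene (0.103) and without KO3 and KO5 (0.0899). Spleen and bone marrow shared 636 higher genes where 158 were expected by chance and 619 lower genes where 144.5 were expected, and their log2 fold changes correlated with r = 0.611 across genes. Spleen and liver shared 32 higher (7.025 expected) and 56 lower (5.222 expected) genes.

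The binding motif of the ZFP36 family, UAUUUAU, was more frequent in the 3' UTRs of genes that rose in the ovary. It was present in 72 of 201 such genes (35.82%) against 29.23% of other tested genes, an odds ratio of 1.62 (95% interval 1.17 to 2.24) at equal UTR length and expression (logistic model, adjusted p = 0.0317). The highest ratio among 20 control 7-mers of the same composition was close to it, at 1.61. The ovary result was lost with the AUUUA pentamer (odds ratio 1.17), with an 8-mer motif (1.42) and in a Fisher exact test without the covariates (1.35). It passed with the shortest 3' UTR (1.72; logistic model, adjusted p = 0.0275). It also passed with AU content in the model, chosen after the data were seen (1.6; logistic model, adjusted p = 0.0421). Genes that rose in bone marrow had an odds ratio of 1.09 (95% interval 0.98 to 1.22; adjusted p = 0.277; highest control 1.06), those in spleen 1.01 (0.87 to 1.17; adjusted p = 0.878) and those in liver 1.26 (0.8 to 1.99; adjusted p = 0.421). Among genes that fell the ratios were 0.73 to 0.89 (adjusted p = 0.252 or more). Lung and kidney had too few called genes for this test.

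**Figure D4:**
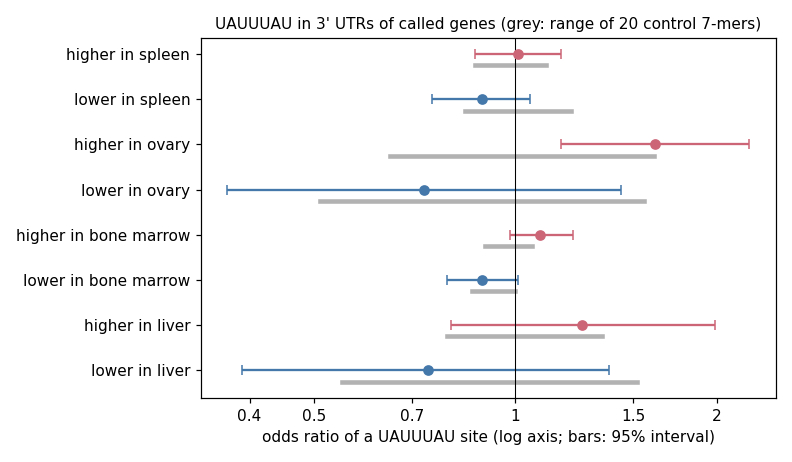
Odds ratios (95% intervals) of the UAUUUAU motif in the 3' UTRs of genes called higher or lower, by tissue. Grey marks show the range of 20 control 7-mers.

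The deposited table of 2111 upregulated genes carried no tissue, so it was compared with genes called higher in any tissue. Of its genes 2101 were tested here, and 1646 were called higher by edgeR in at least 1 tissue (77.97% of those listed), 1998 by DESeq2. Conversely, 47.97% of the 3431 genes called higher in any tissue were listed. Among those that rose by 2-fold or more 1548 of 1827 were listed. Its WT means ranked the genes much like the WT means computed here, with Spearman rho from 0.96 in bone marrow to 0.996 in ovary and lung. By tissue, listed genes made up 155 of 243 genes called higher in ovary, 111 of 130 in liver, 619 of 1159 in spleen and 1245 of 2643 in bone marrow. In lung Apol11b, Gm32051 and Bmp6, and in kidney Epo, were listed. The authors chose the list on these same samples, so being listed is no independent evidence for a call.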

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

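Chosen only after the results were seen were the tests of the neutrophil list's spread and of that list with the sex score, of the T and NK and bone lists against the erythroid list, of liver against lung at 3 libraries, and of the spread in lung and liver against bone marrow. The number of genes called was compared with that under other divisions of the same libraries into groups of the same size. In bone marrow the real division ranked 1 among 100, with 5187 called and at most 5 for any other. Of the other divisions, 13 parted all 5 pairs of replicate numbers, and these called at most 0 genes. In spleen it ranked 1 among 35 (2262 called, at most 1 otherwise). In ovary it ranked 1 among 10 (315 called, at most 1 otherwise) and in lung 1 among 10 (4 called, at most 1 otherwise), but 10 divisions are too few to tell. Kidney ranked 2 among 10: the division that put KO3, KO5 and WT2 together called 4658 genes, against 3 for the real one. That division followed the sign of the first principal component, and 10 divisions could not tell here either. Liver ranked 2 among 100, since the division that put KO1, KO5, WT1, WT2 and WT5 together called 1665 genes against the real 247, again along the sign of the first principal component. In kidney and liver a division unrelated to the genotype thus called more genes than the genotype did.

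The genotype effect differed between tissues for 2516 genes, so the result of a tissue does not stand for the others. The real labels ranked 1 among 21 permutations within tissues, the next calling 2249 genes, and that permutation followed the first principal component of kidney. Of the others, 2 also followed that component and called 60 and 0 genes. Leaving kidney out with the real labels gave 2521 genes, so the number did not rest on kidney. Named genes marked by the same test were Cda (edgeR adjusted p = 4.04e-16), Bmp1 (9.2e-10), Itga2b, Pls1, F13a1, Pf4 and Mmrn1 (9.49e-10 each), Zfp36l2 (3.3e-09), Mpig6b (8.54e-08), Ppbp (3.94e-07), Plod2 (0.00034), Stfa3 (0.00662), Stfa1 (0.0161) and Clca3a1 (0.0358). Stfa3 lost this call without lung, Stfa1 without bone marrow or lung, and Clca3a1 without bone marrow or kidney.

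Some libraries stood far from the others of their group for a named gene, by a gap test at 95%, which marks about 1 in 20 groups by chance. It marked 31 of 322 groups. In spleen these were Kit in WT2 (54.55 CPM, nearest other library 63.32), Elavl2 in WT3b (0.1637, nearest 0.04674), Krt4 in WT3a (0.09201, nearest 0.02339), Clca3a1 in WT3a (130.3, nearest 92.27) and Apol11b in WT1 (128.6, nearest 67.59), the pup of 13 days. Among KO spleens KO4 was apart for Pdgfrb (150.6 CPM, nearest 112.4), Cdh5 (186.2, nearest 121.6), Ly6g6f (0.07894, nearest 0.1759), Clca3a1 (262.1, nearest 165.9) and Serpina3b (0.05921, nearest 0). KO3 was apart for Cel (0.2765 CPM, nearest 0.02561), Ctrb1 (0.4524, nearest 0.128) and Stfa1 (5.379, nearest 41.2), and KO2 for Thbs1 (34.54, nearest 23.87). In bone marrow WT4 was apart for Actn3 (7.8 CPM, nearest 3.802), Myh1 (1.27, nearest 0.5825) and Lexm (0.03, nearest 0), KO3 for Pax5 (164.9, nearest 116.4) and Ptgs2 (2.891, nearest 0.9986), KO4 for Cxcl9 (18.92, nearest 4.736) and Cd3e (13.43, nearest 5.914), and KO5 for Ly6g6f (0.2108, nearest 0.0521) and Gnaz (0.2728, nearest 0.0838). In liver KO4 was apart for Cyp17a1 (148.4 CPM, nearest 22.23), Nnmt (245.9, nearest 29.69) and Fabp4 (316.4, nearest 198.8), KO3 for Orm1 (142.9, nearest 44.2) and Orm2 (2.86, nearest 0.6536) and KO5 for Zfp36l2 (5.076, nearest 2.673). Among WT livers WT4 was apart for Cyp17a1 (1.577 CPM, nearest 0.4915) and Elfn1 (0.1147, nearest 0.06). For the liver genes Cyp17a1, Nnmt, Orm1 and Orm2 the size of the rise thus rested much on 1 library.

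Lower platelet and neutrophil mRNA in KO bone marrow was weighed against 3 explanations. Unequal sex of the libraries was unlikely to be the cause, since the megakaryocyte median was -2.82 with the sex score in the model and -3.00 without it, and the neutrophil median -1.91 and -1.80. Of 20 neutrophil mRNAs 19 lay within 1 log2 unit of their median of -1.80 (range -2.79 to -0.40). Fewer neutrophils of an unchanged kind would lower all of them alike. A window of 1 log2 unit to each side also admits falls of unlike size, so it cannot tell whether the cells were unchanged. A lower share of neutrophils may explain part of the fall, but this stayed open. The stefin genes named in the report were not on that list and fell further (-3.88 to -3.06), but they were named for their small p values and share reads, so they do not decide it. The third explanation was a share shift that moves all other cell types alike. T and NK mRNAs rose by 1.23 on the log2 scale relative to erythroid mRNAs (SD over pairs 1.14), in 5 of 5 pairs (0.23 to 2.92). The mean score of stem and progenitor mRNAs fell by 0.45. These values argue against such a shift, but weakly, since the lists were compared after their values were seen and the pairing came from the data.

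Higher bone mRNA in KO bone marrow was weighed against 2 explanations. With a skeletal muscle score in the model the bone median was 1.52, against 1.73 without it, and 9 instead of 11 members were called. Muscle carried over with the marrow, or tissue that varies with it, was thus unlikely to be the main source. Within groups the muscle and bone scores correlated little (r = 0.14), so the fit cannot speak to bone tissue carried over without muscle. That source was not tested and stayed open. The other explanation was a lower share of the main blood cells, raising everything else alike. Bone mRNAs rose by 1.6 relative to erythroid mRNAs (SD over pairs 0.88), in 5 of 5 pairs (0.74 to 2.8). This argues against a lower share of neutrophils and platelets alone, raising all other cell types alike. These lists too were compared after their values were seen. A lower share of all blood cells stayed open, since erythroid cells are blood cells and it would give the same rise. The exact p within pairs was 0.0625 for both differences, the smallest that 32 arrangements allow.

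The number of called genes differed widely between tissues, and 2 technical sources were weighed. Depth and counting method also differed and were not tested. Totals were 68472691 to 112191532 counts in bone marrow, where reads could count more than once, against 31072568 to 44303816 in ovary. Liver, counted like bone marrow, had 97213613 to 150824063 counts and 247 called genes. The subsets below kept the depth and counting of each library. The number of libraries could not explain the gap between bone marrow and ovary: bone marrow at 3 libraries per genotype had a median of 2963.5 called genes (2454 to 4380 over 20 subsets), against 315 in ovary. Spleen at 3 per genotype had a median of 1262 (459 to 4865) and liver 10.5 (0 to 471), so the higher number of liver than of lung (4) or kidney (3) may come from its 5 libraries. The spread between libraries stayed open for lung: its biological coefficient of variation was 0.9 times that of bone marrow, but without WT2 632 genes were called instead of 4. In liver it was 1.59 times that of bone marrow, so a wider spread may explain part of the lower number there. In simulated counts 19.39% of 2-fold changes were recovered in liver and 8.163% in kidney, against 87.76% and 85.71% of 4-fold changes.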

How the results depend on the processing

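Chosen only after the data were seen were the fits without 2 libraries in kidney and liver, the fits with 1 exonic part per gene, and the motif model with AU content. All other alternatives below were fixed beforehand, and for each the cause was not tested. In spleen the number of called genes was 3479 with the replicate number as a block, and 1130 to 3130 when 1 library was left out. In ovary it was 1061 with DESeq2, 604 without the filter, 66 in the model of all tissues, 936 with age as covariate, 1408 with the block and 25 to 475 when 1 library was left out. In lung it was 774 with DESeq2, 1526 without the filter, 11 in the model of all tissues and 2 to 632 when 1 library was left out. In kidney it was 99 with DESeq2, 43 without the filter, 8 in the model of all tissues, 6 with age and 0 with the sex score as covariate, 305 with the block, 0 to 7 when 1 library was left out and 191 without KO5 and WT2. In liver it was 1041 with DESeq2, 2056 in the model of all tissues, 63 to 325 when 1 library was left out and 100 without KO3 and KO5. In lung and spleen the median log2 fold change was -0.335 and -0.118 in DESeq2, over more genes than edgeR's -0.016 and -0.02.

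The fall of Zfp36l2 in kidney passed in some fits and not in others. It passed with a log2 fold change of -1.99 in DESeq2 (adjusted p = 3.16e-16), -2.00 with RLE scaling (edgeR adjusted p = 0.0463), -1.97 without the filter (0.000124), -1.96 in the model of all tissues (5.24e-06), -1.89 with age as covariate (0.0441), -1.90 with the block (4.24e-12) and -1.89 without KO5 and WT2 (1.02e-05). It did not pass with the sex score as covariate (-1.74, edgeR adjusted p = 0.955) or at a mean count of at least 50 (-1.99, 0.0555). Leaving out 1 library gave -2.09 to -1.87, which passed without WT2 (-1.89, edgeR adjusted p = 0.0417) but not without KO3 (0.392), KO4 (0.0973), KO5 (0.281), WT3 (0.201) or WT4 (0.322). The sign of the paralogs turned in some fits, though none passed in either direction. Zfp36l1 in spleen was at -0.05 with the block and -0.03 to 0.17 when 1 library was left out, below 0 without KO4 (-0.01) and WT3a (-0.03). In kidney Zfp36l1 was at -0.19 with the sex score and -0.07 to 0.38 when 1 library was left out, below 0 without KO5 (-0.07) and WT3 (-0.01). Zfp36 in kidney was at -0.59 with the sex score, -0.20 with the block, -0.17 without KO5 and WT2 and -0.24 to 0.22 when 1 library was left out, below 0 without KO5 (-0.24) and WT4 (-0.04). In liver Zfp36 was at -0.10 to 0.28 when 1 library was left out, below 0 without KO3 (-0.02), KO4 (-0.02) and WT5 (-0.10).

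Outside bone marrow some libraries with the same replicate number had the same labelled day and others did not, and not every library correlated best with its own number, as the libraries of bone marrow did. No paired analysis was possible in lung because KO and WT shared only 1 number. In liver the block gave 252 called genes and in bone marrow 6372, where it changed no named call and no list call. With the block the calls of Ctrb1, Cel and Cpa1 in spleen (edgeR adjusted p = 0.0761 to 0.128), of Satl1 in ovary (0.245) and of Nnmt, Ppbp and Plod2 in liver (0.0528 to 0.0705) ended. With the block the list tests called 12 lists in spleen, 10 in ovary and 14 each in bone marrow, kidney and liver. The hypoxia (camera adjusted p = 0.103) and endothelial lists (0.0627) in spleen and the granulosa (0.0739) and cell cycle lists (0.158) in ovary passed without it but not with it. In kidney so did those of cell cycle, T and NK cells, cholesterol and endothelial mRNAs (camera adjusted p = 0.0935 to 0.135). Passing only with it were the cell cycle, erythroid, B cell, T and NK cell and interferon lists in spleen (camera adjusted p = 0.000115 to 0.0233) and the immediate early, mitochondrial and theca lists in ovary (2.95e-07 to 0.00844).

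With an estimated correlation 0 lists passed in spleen, ovary, bone marrow, lung, kidney and liver, against 9, 9, 14, 12, 18 and 14 at the preset correlation. With fry 7 passed in spleen, 2 in ovary, 9 in bone marrow, 0 in lung, 1 in kidney and 4 in liver. The test between tissues called 687 genes without bone marrow. Genes called in the same direction in several tissues were 453 at adjusted p below 0.01, 2173 at adjusted p below 0.1 and 2339 with DESeq2.

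Apart from the block, the fits that moved the fold of a named gene by over 1.5 times, though not its sign, were these (log2 fold change). In spleen they were those of Kcnj5 without KO1 (-8.35), Retnlg without KO2 (-2.6), Ctrb1 (-9.13) and Cel (-10.22) without KO3, Serpina3b without KO4 (-10.23), C2cd4a (5.8) and Krt4 (5.68) without WT3a, Elavl2 without WT3b (5.57) and Krt4 with age (4.28). In ovary they were those of Pde6b (-3.27) and Insm1 (-4.12) without KO1, Myt1 without KO2 (2.61), Satl1 without WT1 (5.03) and Otop3 without WT3 (3.74). In bone marrow Ptgs2 was at -3.36 without KO3, Cxcl9 at 3.46 without KO4, Lexm at 9.6 without WT4, and Fgf23 at 3.79 without KO5 and 5.64 without WT2. The platelet genes Treml1, Ppbp, Gp6, Mpig6b, Gnaz and Ly6g6f were at -6.39 to -5.45 without KO5. In lung Cxcl10 was at 1.13 without KO2. In liver Orm1 was at 4.67 and Orm2 at 3.11 without KO3, Nnmt at 3.16, Hamp at 3.99, Cyp17a1 at 4.52 and Fgf23 at 5.19 without KO4, Hamp at 5.39 without WT2, and Cyp17a1 at 6.7 and Fgf23 at 6.78 without WT4. Without KO3 and KO5 Orm1 was at 4.76 and Orm2 at 3.17. With 1 exonic part per gene Zfp36l2 was at -6.28 in bone marrow and -3.6 in liver, Pianp in bone marrow at 3.27 and Cyp17a1 in liver at 5.34.

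The motif's odds ratio turned or moved with the test. For genes higher in spleen it was 0.9 with the pentamer (adjusted p = 0.398) and 1.22 in a Fisher exact test (adjusted p = 0.00741). For genes lower in spleen these were 0.79 (adjusted p = 0.0207) and 0.73 (adjusted p = 0.000217). For genes higher in ovary the pentamer gave 1.17 (adjusted p = 0.535), the 8-mer 1.42 (adjusted p = 0.0952) and the Fisher exact test 1.35 (adjusted p = 0.0572), and for genes lower in ovary the pentamer gave 1.13 (adjusted p = 0.718). Genes higher in bone marrow had 0.9 with the pentamer (adjusted p = 0.237), 1.19 with the shortest UTR (adjusted p = 0.0275), 1.3 in the Fisher exact test (adjusted p = 1.57e-06) and 1.16 with AU content in the model (adjusted p = 0.0436). Genes lower in bone marrow had 0.84 with the pentamer (adjusted p = 0.0207), 0.84 with the 8-mer (adjusted p = 0.0226) and 0.81 in the Fisher exact test (adjusted p = 0.000448). Genes higher in liver had 1.93 with the shortest UTR (adjusted p = 0.0275), and genes lower in liver 0.36 in the Fisher exact test (adjusted p = 0.000448).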

Other observations

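Chosen only after its result was seen was the test of red cell RNA in kidney. Monocyte and macrophage mRNAs were higher by the list test in ovary, kidney and liver as well. In ovary 8 of 16 members were higher and 1 lower adjusted over the list alone, with no call over all genes (median 0.53, camera adjusted p = 0.00111, and 0.47 with an estimated correlation). Kidney had 2 of 19 higher adjusted over the list alone (median 0.58, camera adjusted p = 1.27e-06, and 0.1 with an estimated correlation), and liver 2 higher and 2 lower of 20 (median 0.61, camera adjusted p = 0.0417, and 0.57 with an estimated correlation). Interferon response mRNAs were higher in liver (median 0.79, 1 of 18 adjusted over the list alone; camera adjusted p = 0.00964, and 0.63 with an estimated correlation) and in kidney (median 0.23, 0 of 19; camera adjusted p = 3.3e-06, and 0.15 with an estimated correlation).

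The median of the adipocyte list differed in sign between tissues, which was not tested between them. Beside the lower values in ovary given above, in bone marrow 4 of 8 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.95, camera adjusted p = 0.0341, and 0.4 with an estimated correlation), while in kidney the median was -1.36 with 0 of 10 lower adjusted over the list alone (camera adjusted p = 3.3e-06, and 0.13 with an estimated correlation). In liver 1 of 5 rose, with all values higher in KO (median 1.28, camera adjusted p = 0.00458, and 0.23 with an estimated correlation). Cell cycle mRNAs fell in 6 of 24 members in bone marrow, 6 adjusted over the list alone (median -0.18, camera adjusted p = 0.0142, and 0.57 with an estimated correlation). Erythroid mRNAs did not pass in bone marrow (median -0.06, camera adjusted p = 0.392, and 0.8 with an estimated correlation) or spleen (median 0.05, camera adjusted p = 0.729, and 0.99 with an estimated correlation). In kidney their median was -0.27, with 0 of 19 lower adjusted over the list alone (camera adjusted p = 0.000105, and 0.32 with an estimated correlation).

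Epo in kidney and Fgf23 in spleen, bone marrow and liver were called higher in KO. The hypoxia list passed in liver and kidney at the preset correlation and with fry (adjusted p = 0.0084 and 0.033) but not with an estimated correlation (adjusted p = 0.097 and 0.1), with 4 of 18 members called in liver and 0 of 18 in kidney. In spleen the list also passed both (camera adjusted p = 0.0421, fry adjusted p = 0.047) but not with an estimated correlation (0.47), with 3 of 18 members called. In bone marrow, where Fgf23 was called too, it passed neither (median 0.14, camera adjusted p = 0.516, fry adjusted p = 0.34), with 3 members called higher and 3 lower. A lack of red cells or oxygen could link the rises of Epo and Fgf23, since both raise these genes, but the list did not go with Fgf23 in marrow. As a test, the mean log2 fold change of 4 globin mRNAs in kidney was -0.83, but KO libraries (7.04 to 8.12 log2 CPM) met the range of WT libraries (8.12 to 8.85), so it cannot tell. Blood counts and haemoglobin of the same pups would test this directly. The Epo call itself ended with the sex score in the model and without KO3, KO5, WT3 or WT4.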
